A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

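RNA was measured in 4 libraries of the budding yeast Saccharomyces cerevisiae, 1 per group: total RNA and RNA of the cytoplasmic fraction from wild type cells and from hrp1-1 cells. Per the labels, cultures grew overnight at 25 °C and were held at 37 °C for 3 hours, and libraries were made from 200 ng of RNA with a modified stranded total RNA kit. Groups were taken from the sample titles. HISAT2 and the sacCer3 genome build are named in the submitters' processing notes, without a version of the aligner. How reads with several matches were treated is not given in the sources used here.

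The authors deposited coverage: raw signal values per base in windows around transcript ends, reaching 200 nt to each side, with 400 wild type values followed by 400 hrp1-1 values on each line. Per the file headers, the lines form 4 blocks, for the + and - strand of the cytoplasmic and of the total RNA. The mutant part of the cytoplasmic - strand block has a header that names both genotypes, and it was read as hrp1-1 because each of the other 3 blocks has hrp1-1 there. The blocks hold 61250, 61322, 61220 and 61266 windows around 122591 distinct ends. No normalisation of the deposited coverage is named in the sources used here, and the library means differ, so the values were treated as raw. How the transcript ends were chosen is also not given in the sources used here.

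Values of 10000 or more had been rewritten in the deposited table, to 3 digits. In 244114 values a decimal comma had been read as a digit separator, so that the exponent was too large by 3, and these were divided accordingly. Another 437 values had a comma without that shift, 25385 were written with a point and an exponent, and 24 values were not numbers and were left out. The windows were then joined into 1 track per library and strand. Across 169444340 comparisons of bases present in several windows, 0 conflicted, which checks the joining and not the size of the rewritten values. That size was checked at 851 neighbouring bases on both sides of 10000. Their ratio had a median of 1.05, 40 pairs had a ratio above 1.5, and the highest was 785. Large ratios also arise at the edges of abundant RNAs, and the original values are not known.

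The joined tracks covered 6633126 strand-specific bases. On the nuclear chromosomes, this was 27.5% of both strands up to the last annotated gene. Genes came from a table of 6477 genes on the assembly that sacCer3 is built from. It holds coding spans with no introns and no untranslated regions, and strands were read from the locus tags of 6452 genes. As the file covers only windows, a gene or window was used where at least 100 of its bases were covered, or 20 for small RNAs. These minimums were set after the files were seen. The gene level lists and markers also held protein-coding genes with fewer than 100, among them MFA1 with 60 and SAG1 with 67 covered bases. The intron coverage index and the list of intron-containing genes, both planned, were not run, because intron positions were not used here. Levels of intron-containing genes therefore average any covered intron bases with the coding bases.

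Each library was scaled so that the average covered coding base of nuclear protein-coding genes had a normalised coverage of 100. Before scaling, that base had a coverage of 240.8 in wild type total, 282 in wild type cytoplasmic, 129.2 in hrp1-1 total and 168.1 in hrp1-1 cytoplasmic RNA. Of 17932 isolated stretches of coverage, 9136 were 51 nt long, which was taken as the read length, and coverage sums divided by it gave approximate reads. A floor of 3 such reads in a window of 250 nt corresponds to a normalised coverage of 0.254 in wild type total, 0.217 in wild type cytoplasmic, 0.474 in hrp1-1 total and 0.364 in hrp1-1 cytoplasmic RNA. Reads carry no molecular identifiers here, so these floors cover counting error only.

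The readthrough index was log2 of downstream over coding coverage, each with a pseudocount of 0.5. Downstream coverage was the mean over the 250 nt that follow the first 150 nt after the stop codon, and coding coverage the mean over the last 500 coding nt. Of 6002 nuclear protein-coding genes, 4835 had enough covered coding bases and, counted separately, 4251 had no gene on the same strand within 450 nt downstream. Of the latter, 2991 had both windows covered, and 2611 also had a mean coding coverage of at least 10 over the 4 libraries. An upstream control used the mirrored window before the start codon, relative to the whole coding sequence. The snoRNA 3' extension compared the 200 nt that follow the first 50 nt after the annotated end with the snoRNA body, for snoRNAs with no gene on the strand within 300 nt. Gene level was the mean coding coverage, compared on the log2(value + 0.5) scale, which understates the change of low genes. Its counts and rankings used genes with a mean coding coverage of at least 10 over the 4 libraries.

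With 1 library per group there was no test: each comparison gives values, log2 ratios, and counts of genes changed by at least 1 log2 unit. Intervals are 95% bootstrap intervals of a median from 2000 draws of genes, which describe the spread over genes of these libraries and not replicate error. Gene lists, 24 in all, were placed by the percentile of their median among 10000 random lists of the same size, drawn from genes of similar mean coverage. SCR1 alone got no percentile, and for the index neither did the alpha-specific genes, with 2 members used, or the lists of RNA genes and mitochondrial genes, with none. They were cleavage and polyadenylation factors, Nrd1-Nab3-Sen1 (NNS) termination factors with the nuclear exosome, mRNA export and guard proteins, NNS-attenuated genes, heat shock chaperones, general stress genes, ribosome biogenesis, cytosolic ribosomal proteins, glycolysis, histones, nuclear-encoded respiration, secretory and plasma membrane proteins, Gcn4-regulated amino acid synthesis, ergosterol synthesis, the phosphate regulon, cell wall integrity, a-specific genes, alpha-specific genes, common auxotrophy markers, mitochondrially encoded genes, nuclear RNA markers, the signal recognition particle RNA SCR1 as a cytoplasmic marker, snoRNAs and tRNAs. The gene table lists the attenuated gene FKS2 as GSC2.

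Genes were named by rules fixed before the data were examined, as were the lists, the comparisons of the report and most alternatives. Some tests of explanations were chosen later, and the closing section names them. For the index these were the 15 largest rises and 5 largest falls, ranked by the smaller change of both fractions. For gene level they were the 12 largest rises and 12 largest falls in both fractions, and for the fractions the 5 largest rises and 5 largest falls of cytoplasmic over total RNA in both genotypes. The 5 snoRNAs with the largest rise of 3' extension, up to 4 members of each list, and HRP1, SCR1, TLC1 and ACT1 were added. Alternatives changed the pseudocount, the coverage minimum, the window, the coding part, the scaling and the distance to other genes. Those chosen after seeing the data were a window past the farthest listed end and subtraction of background coverage. Genes whose next gene on the strand lies over 1500 nt away, and other pseudocounts for the index by expression level, were also chosen then. Background was the library's median coverage opposite to 826 downstream windows with no gene on either strand. It was 0.667 in wild type total, 0.620 in wild type cytoplasmic, 1.083 in hrp1-1 total and 1.787 in hrp1-1 cytoplasmic RNA. The wild type values exceed the median downstream coverage there, 0.656 and 0.396, so many wild type windows became 0. In wild type, results after subtraction therefore rest largely on the pseudocount.

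The steps were tested on simulated data first. The index step held 2481 genes. For the index in total RNA, 97.9% of 95 genes simulated with a 4-fold rise passed 1 log2 unit upwards. So did 31.3% of 96 genes with a 2-fold rise, and 3.78% of 2169 unchanged genes passed it in either direction. In cytoplasmic RNA these shares were 95.8%, 30.2% and 2.77%. The genes with a simulated rise of the index were drawn from those above a minimum of downstream reads in wild type total RNA. Recovery in genes with fewer downstream reads was not measured, and 290 of the 2611 genes had no downstream coverage in that library. All simulated libraries were built from wild type total counts with counting noise only, so the cytoplasmic shares differ from the total ones by depth alone. For gene level, all 100 genes with a 4-fold change passed in both fractions, against 0% of 3488 unchanged genes. Of 98 genes with a 2-fold change, 9.18% passed in total and 8.16% in cytoplasmic RNA. All simulated changes were rises, and the scaling then lowered every gene. In total RNA the median fold was 0.927 for unchanged genes and 1.85 for genes with a 2-fold change. These shares hold for that shift, and do not measure how many 2-fold changes the counts below miss. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.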

Results

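Hrp1 is an RNA-binding protein of yeast cleavage factor IB, part of the machinery that cuts pre-mRNA at its 3' end before polyadenylation, and hrp1-1 is a temperature-sensitive mutant. Stranded RNA coverage was available for 4 libraries, 1 each of wild type total, wild type cytoplasmic, hrp1-1 total and hrp1-1 cytoplasmic RNA, all after 3 hours at 37 °C. With 1 library per group there was no replicate error to compare with, no p-value was computed, and every difference below is between libraries. The covered windows held about 13555680, 13134492, 11398567 and 10483176 reads in that order. Nuclear coding bases took 64.1%, 77.4%, 40.9% and 57.8% of the coverage. SCR1, the RNA of the signal recognition particle, took 12.7%, 3.79%, 29.6% and 9.71%, and mitochondrial RNA 2.92%, 0.757%, 7.28% and 3.38%. The mean coverage of SCR1 before scaling lay above 10000 in every library, in the range of the rewritten values. Its levels, these shares and the scaling to all coverage therefore depend on that repair.

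HRP1 itself (chromosome XV, 87844 to 89448, + strand) was covered far more in hrp1-1. Its normalised coverage, on a scale where the average coding base has 100, was 47.0 in wild type total and 48.9 in wild type cytoplasmic RNA. In hrp1-1 it was 1168 in total and 1483 in cytoplasmic RNA, a rise of 24.6-fold and 30.01-fold. Coverage does not show the mutated bases, so the level of HRP1 neither checks nor contradicts the genotype labels. The genes on either side did not share the rise, with log2 changes in total and cytoplasmic RNA of -0.81 and -0.34 for TRM11 and -0.70 and 0.11 for SMF1.

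The genotypes also differed in marker genes of mating type and auxotrophy. The a-factor gene MFA2 was at 650 in wild type total and 26.1 in hrp1-1 total RNA, while the alpha-factor gene MF(ALPHA)1 was at 1.55 and 302 and the a-factor receptor gene STE3 at 2.52 and 66.7. The median log2 change of 5 a-specific genes was -2.66 in total and -0.18 in cytoplasmic RNA, and that of 3 alpha-specific genes was 4.48 and 4.57. Of the 6 auxotrophy markers that entered that list, with medians of -0.56 and -0.81, URA3 was listed at 0 in wild type total RNA and at least 5934-fold higher in hrp1-1. Wild type cytoplasmic RNA had about 2 URA3 reads, against 16505 in hrp1-1. MET17 was listed at 0 in both wild type libraries and was at least 340.8-fold higher in total and 556.9-fold higher in cytoplasmic hrp1-1 RNA. LYS2 was listed at 0 in both hrp1-1 libraries and was at least 174.9-fold and 241-fold lower there. LEU2 was listed at 0 in all 4 libraries. Of 15 markers with coverage, 7 differed by at least 3 log2 units in both fractions, so that genotype and strain background differ together in every comparison of hrp1-1 with wild type.

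**Figure D1:**
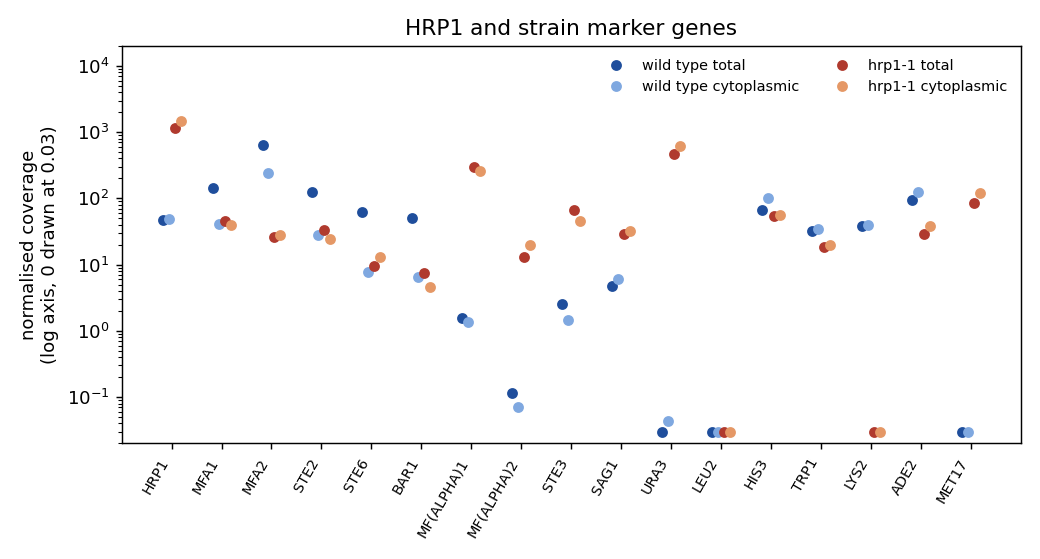
Normalised coverage (log axis, average coding base 100, values of 0 drawn at the bottom) of HRP1 and of mating type and auxotrophy markers, with 1 point per library. HRP1 lies at 47.0 and 48.9 in wild type and at 1168 and 1483 in hrp1-1, and MF(ALPHA)1, URA3, MET17 and LYS2 separate the genotypes.

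The series asks whether RNA that extends past the normal 3' end is found in hrp1-1 and in its cytoplasm. In total RNA, coverage downstream of coding genes was higher in hrp1-1. The histone H3 gene HHT1, the aldolase gene FBA1, the ribosomal protein genes RPS30B, RPL16A and RPS1B, and the chaperone genes SSB2 and SSE1 were among those with the largest rises. Over 2611 genes, downstream coverage had a median of 1.69% of coding coverage in wild type and 7.39% in hrp1-1. Pooled over these genes, it was 3.69% and 6.65%. The readthrough index, the log2 ratio of downstream to coding coverage, had medians of -4.70 and -3.42. Per gene it changed by a median of 1.04 log2 units (95% bootstrap interval over genes 0.96 to 1.12, quartiles 0.08 and 2). It rose by at least 1 in 1334 genes and fell by as much in 107. The rises, here and in cytoplasmic RNA, include genes whose index rose through a lower coding level alone. HO had 0 downstream reads in all 4 libraries and changed by 2.97 and 2.55 in total and cytoplasmic RNA. URA4 went from about 7 and 5 downstream reads to 0 and 0, and changed by 2.40 and 3.51. How many rises are of this kind was not counted. The index 50 to 200 nt past the stop codon changed by a median of -0.03. The farthest listed transcript end lay at a median of 205 nt after the stop codon, within the downstream window. That window therefore also holds coverage before listed ends in many genes, and not readthrough alone. In a window past the farthest listed end the median change was 1.35. For the main window, subtracting background coverage left a median of 0.80, with 183 genes down.

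Cytoplasmic RNA showed the same direction. ACT1, the actin gene, changed by 4.26 log2 units there and by 3.54 in total RNA, and FBA1 by 7.82 and 5.36. Median downstream coverage was 1.31% of coding coverage in wild type and 10.2% in hrp1-1 (pooled over genes, 2.71% and 8.73%), and the median index was -4.56 and -3.10. Per gene the index changed by a median of 1.28 (0.33 and 2.31 quartiles, interval 1.2 to 1.35), with 1482 genes up and 77 down by at least 1. In both fractions, 1104 genes rose, where independent lists would share 757.2, and 27 fell, against 3.16. Total RNA includes cytoplasmic RNA, and both comparisons use the same genotypes and genes. The lists are therefore not independent, and this excess carries no weight of its own. Across genes, which are not independent replicates, the changes in both fractions had a Spearman rho of 0.74. Background subtraction lowered the cytoplasmic median to 0.71, with 218 genes down, and a pseudocount of 2 lowered the medians of both fractions to 0.62.

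Past the farthest transcript end listed within 400 nt of the stop codon, wild type coverage was close to 0 and hrp1-1 coverage stayed level. In the stretch 51 to 100 nt past that end, the median over 2605 genes was 0.435% of coding coverage in wild type total and 0.0881% in wild type cytoplasmic RNA. In hrp1-1 it was 5.11% in total and 6.96% in cytoplasmic RNA. How the ends were chosen is not given in the sources used here, and ends taken from wild type reads would lower the wild type values past them.

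**Figure D2:**
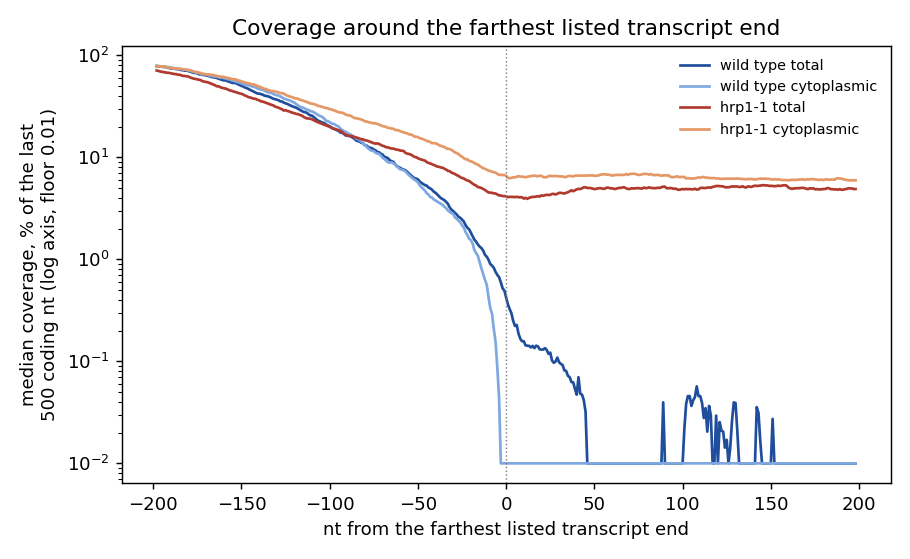
Median coverage per base, in % of coverage in the last 500 coding nt (log axis, lower values drawn at the floor), against distance in nt from the farthest listed transcript end, with 1 line per library over 2605 genes. Both wild type lines drop to the floor past the end, while the hrp1-1 lines continue, at medians of 5.11% and 6.96% in the stretch 51 to 100 nt past it.

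**Figure D3:**
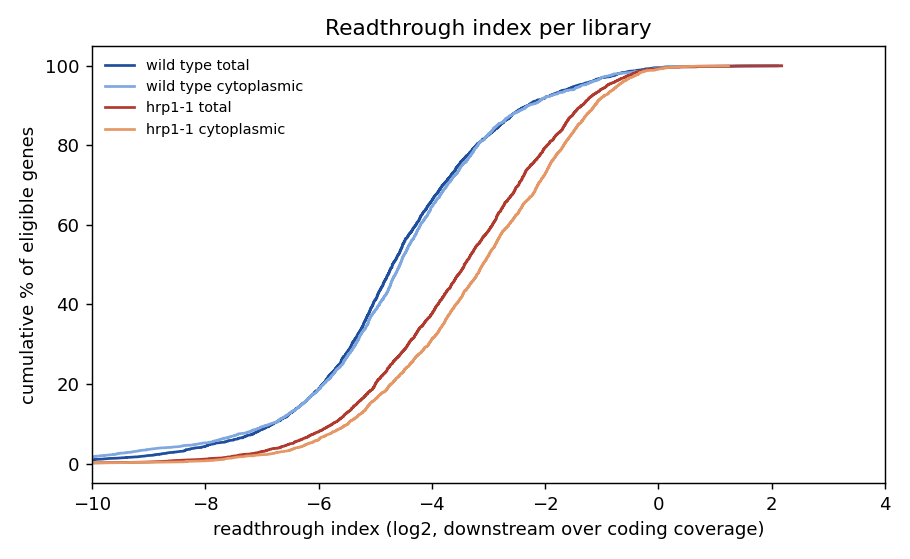
Cumulative share of the 2611 genes (in %) against the readthrough index (log2 of downstream over coding coverage), with 1 line per library. The hrp1-1 lines lie to the right of the wild type lines, with medians of -3.42 and -3.10 against -4.70 and -4.56.

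HHT1 (chromosome II, 256331 to 256741, + strand) had about 4 and 2 downstream reads in wild type total and cytoplasmic RNA, and 284 and 354 in hrp1-1. Downstream coverage went from 0.0462% and 0.0211% of coding coverage to 7.23% and 8.59%, and its index rose by 6.04 and 6.72. FBA1 (chromosome XI, 326408 to 327487, - strand) went from about 49 and 19 downstream reads to 1171 and 2710. RPS30B rose by 5.23 and 7.07, RPL16A by 5.06 and 5.18, RPS1B by 5.05 and 6.42, and EGD1, a subunit of the nascent polypeptide-associated complex, by 4.97 and 5.74. SSB2 rose by 4.96 and 5.55, SSE1 by 4.91 and 5.63, the ATPase gene CDC48 by 5.20 and 4.87, and the cyclophilin gene CPR1 by 4.82 and 4.92, although CPR1 in total RNA was at -0.06 in the window 50 to 200 nt past the stop codon. The other named rises were ARO8 (4.80 and 5.23), ADH3 (4.78 and 5.10), RPB4 (4.75 and 5.79) and KRS1 (4.61 and 5.02). LYS2 ranked highest by value, but its coding region was listed at 0 in hrp1-1, with about 5 and 2 downstream reads, so its index carries no readthrough. Several of these genes have near-identical copies, among them HHT1, RPS30B, RPL16A, RPS1B and SSB2, and the split of reads between copies is uncertain. The farthest listed ends of the named rises lay from 123 nt (RPS30B) to 391 nt (EGD1) after the stop codon, in part inside the downstream window.

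**Figure D4:**
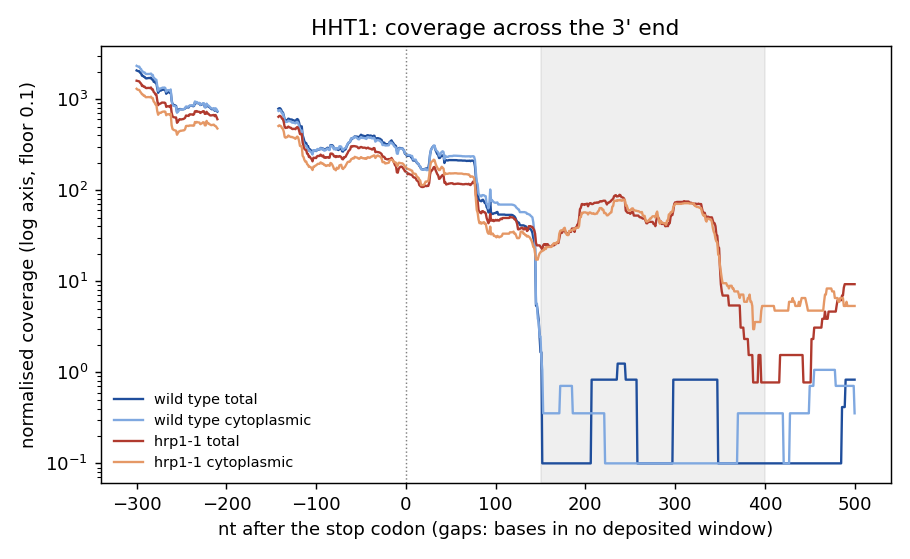
Normalised coverage (log axis, lower values drawn at the floor) at HHT1 against nt after the stop codon, with 1 line per library and the downstream window shaded. In the window the wild type lines hold about 4 and 2 reads and the hrp1-1 lines 284 and 354.

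Coding coverage is the denominator of the index, and the 5 named falls all had a higher coding level in hrp1-1. The index of MF(ALPHA)1 changed by -3.48 and -3.17 in total and cytoplasmic RNA, YCR041W by -3.23 and -3.11, ATG10 by -3.03 and -3.67, YCL021W-A by -3.39 and -2.45, and the mating regulator gene KAR4 by -4.74 and -2.35. MF(ALPHA)1, YCR041W and ATG10 had 3 or fewer downstream reads in wild type. HRP1 changed by -2.28 and -2.01, with 3 and 0 downstream reads in wild type.

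Among the gene lists, 17 heat shock chaperones had a median index change of 2.57 in total and 3.92 in cytoplasmic RNA, the 98.4 and 99.9 percentiles of matched random lists, and 13 and 14 of them rose by at least 1. SSE1 and STI1 (3.88 and 4.59) were the highest. Ribosomal protein genes (93) had medians of 1.56 and 3.06, percentiles 51.9 and 97.5, and glycolytic genes (14) had 2.36 and 3.15, percentiles 91.6 and 82.4. Histones (9) had 1.95 and 2.07, percentiles 71.9 and 36.9. Nuclear-encoded respiration genes (17) had 0.28 and 1.36, percentiles 2.0 and 13.6, with ATP1 at 3.47 and 4.22 and SDH3 at -1.48 and 1.42. Genes of secretory and plasma membrane proteins (20) had 1.33 and 0.56, percentiles 47.4 and 0.2.

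The next comparison asks whether extended RNA is found in the cytoplasmic fraction in the same proportion as in total RNA. Within wild type, the index differed between cytoplasmic and total RNA by a median of -0.01 over 2611 genes, with 228 genes higher and 203 lower by at least 1. In hrp1-1 the median was 0.30 (interval 0.26 to 0.33), with 435 higher and 126 lower. Ribosomal protein genes moved apart, with a median of -0.63 in wild type and 0.64 in hrp1-1, and heat shock chaperones had -0.12 and 0.82. Other lists went the other way, with secretory and plasma membrane protein genes at 0.92 and 0.28, cell wall integrity genes at 0.57 and 0.41, the 4 phosphate regulon genes at 0.77 and -0.40 and the 3 a-specific genes at 3.35 and 0.30. Coding levels of these phosphate and a-specific genes were lower in the wild type fraction than in total RNA, such as STE6 (7.66 and 63.1) and PHO8 (7.78 and 30.4). Coding coverage is the denominator, so these values do not by themselves show more extended RNA in the wild type fraction. The per-gene difference between the genotypes had a median of 0.29 (0.24 to 0.34), but it was 0.56 with a pseudocount of 0.1, 0.07 with a pseudocount of 2, and -0.01 after background subtraction. It was 0.51 with a coverage minimum of 30 and 0.11 past the farthest listed end.

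Nuclear RNA in the cytoplasmic fraction differed between the genotypes. Over 69 snoRNAs, spliceosomal RNAs and other nuclear RNAs, cytoplasmic over total RNA had a median log2 ratio of -1.31 in wild type (-1.72 to -1.13), with 64 of them lower in the fraction. In hrp1-1 it was -0.16 (-0.31 to 0.30), with 36 lower. The median of the per-RNA differences between the genotypes was 1.3. The 61 snoRNAs among them were at -1.29 in wild type and 0.12 in hrp1-1, the latter at -0.08 when scaled by the median of ratios, and the 8 spliceosomal and other nuclear RNA markers at -1.75 and -1.26. Within these markers, the telomerase RNA TLC1 was at -1.23 and 0.31. SCR1, the marker chosen for the cytoplasm, was lower in the fraction too, at -2.02 and -2.11, so a low ratio is not specific to nuclear RNA. A higher ratio in hrp1-1 was not specific to nuclear RNA either. The 3 mitochondrially encoded genes were at -1.18 in wild type and 0.16 in hrp1-1, and secretory and plasma membrane protein genes at -1.67 and -0.90. Among lists that went the other way were heat shock chaperones (0.14 and -0.18), histones (0.07 and -0.32) and glycolytic genes (0.27 and -0.05). The higher snoRNA ratio in hrp1-1 stands beside each cytoplasmic result here.

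The upstream control, the mirrored window before the start codon, also rose. Over 1274 genes the median change was 0.49 in total RNA (0.41 to 0.58) and 0.56 in cytoplasmic RNA (0.46 to 0.66), below the 1.04 and 1.28 of the downstream window, which was measured on another set of genes.

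At the level of gene expression, changes were ranked among genes with a mean coding coverage of at least 10. The 12 largest rises in hrp1-1 included, besides URA3, MET17, MF(ALPHA)1, HRP1 and STE3, the chaperone gene SSA3, the stationary phase genes SPG1 and SPG4, and the copper transporter gene CTR2. MF(ALPHA)2, below that minimum, rose by 4.44 and 5.12 log2 units. SSA3 went from 14.3 to 701 in total and from 11.2 to 536 in cytoplasmic RNA. SPG4 rose by 6.87 and 4.92 log2 units, SPG1 by 5.76 and 5.10, CTR2 by 4.59 and 5.13, ATG10 by 4.3 and 4.37, DPA10 by 4.28 and 4.46, and YAL037W by 4.26 and 4.68. Besides LYS2 and MFA2, the 12 largest falls were the dihydroorotase gene URA4 (-3.79 and -4.03), the cell wall gene FIT2 (-3.75 and -3.42), ARO10 (-4.15 and -2.96) and ARO9 (-2.32 and -2.18) of aromatic amino acid breakdown, and the purine synthesis gene ADE17 (-2.84 and -3.20). HO (-2.97 and -2.55), RAD33 (-2.80 and -2.11), CWP1 (-2.48 and -2.05), BNA5 (-3.13 and -1.99) and HIS4 (-2.04 and -1.97) were the others. ACT1 changed by -0.24 and -0.43.

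Of 4123 genes, 436 rose and 289 fell by at least 1 log2 unit in total RNA, around a median of 0.00. Scaled to all coverage in the file, 149 rose and 1240 fell, so that the rising share of calls was 60.1% or 10.7%. In cytoplasmic RNA 950 rose and 128 fell, around a median of all genes of 0.45, to which the cytoplasmic values here are to be compared. Scaled by the median of ratios, 379 rose and 436 fell, so that the rising share was 88.1% or 46.5%. In both fractions, 378 genes rose, against 100.5 for independent lists, and 98 fell, against 8.97, although lists from total and cytoplasmic RNA are not independent. The Spearman rho across genes was 0.76. As strain background differs with genotype, none of these changes can be assigned to hrp1-1 alone.

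Heat shock chaperones (27) had a median change of 0.99 in total and 0.62 in cytoplasmic RNA, percentiles 100 and 99.9 of matched lists, and 13 and 11 of them rose by at least 1. Scaled by the median of ratios the medians were 0.93 and 0.13, with 12 and 8 up, and scaled to all coverage 0.35 and 0.20, with 8 and 8 up. HSP30 went from 5.94 to 618 in total RNA and from 9.46 to 119 in cytoplasmic RNA, while AHA1 changed by -0.16 and -0.53. Histones (10) were at medians of -0.91 and -1.03, percentiles 0.1 and 0.0, or -1.56 and -1.45 when scaled to all coverage, with HTB2 at -1.57 and -2.22. Cytosolic ribosomal protein genes (138) were at -0.46 and -0.50, percentiles 0.2 and 0.0, and 5 and 4 of them fell by at least 1, among them RPL8A (-1.18 and -1.06). Scaled by the median of ratios these medians were -0.52 and -0.99, with 6 and 68 down, and scaled to all coverage -1.1 and -0.92, with 90 and 53 down. Ribosome biogenesis genes (34) were at -0.50 in total RNA, percentile 0.1, and at 0.01 in cytoplasmic RNA, percentile 1.5, where the median was -0.48 when scaled by the median of ratios, -0.41 when scaled to all coverage and -0.33 without the 5% most covered genes. Their lowest member was DBP2 (-2.40 and -0.89). Glycolytic genes (17) were at -0.15 and -0.45, or -0.80 and -0.87 when scaled to all coverage, with CDC19 at 1.07 and 0.78 and HXK2 at -1.80 and -1.93.

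Nuclear-encoded respiration genes (27) had medians of 0.59 and 0.69, percentiles 100 and 100, or -0.05 and 0.27 when scaled to all coverage and 0.54 and 0.20 when scaled by the median of ratios, and SDH3 changed by 1.33 and 1.2. The 3 mitochondrially encoded genes with coverage were at 1.02 and 2.5. Cell wall integrity genes (20) were at 0.37 and 0.95, percentiles 98.8 and 100, or -0.27 and 0.53 when scaled to all coverage, with PIR3 at 2.77 and 1.37, SLT2 at 1.94 and 1.03 and CWP1 falling. General stress genes (22) were at 0.04 and 0.11, and both medians were below 0 when scaled to all coverage, at -0.61 and -0.31, or by the median of ratios, at -0.02 and -0.38. They went both ways, with DDR2 at 3.32 and 3.57 and GPH1 at -1.89 and -1.01. Cleavage and polyadenylation factors (18) were at 0.23 and 0.76, the first at -0.40 when scaled to all coverage, and besides HRP1 the highest was MPE1 (1.63 and 1.88). Termination and exosome genes (24) were at 0.06 and 0.45, or -0.58 in total RNA when scaled to all coverage and -0.02 in cytoplasmic RNA when scaled by the median of ratios. The 7 NNS-attenuated genes were at 0.10 and 0.77, the first at -0.54 when scaled to all coverage, with ADE12 at -1.77 and -1.39.

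**Figure D5:**
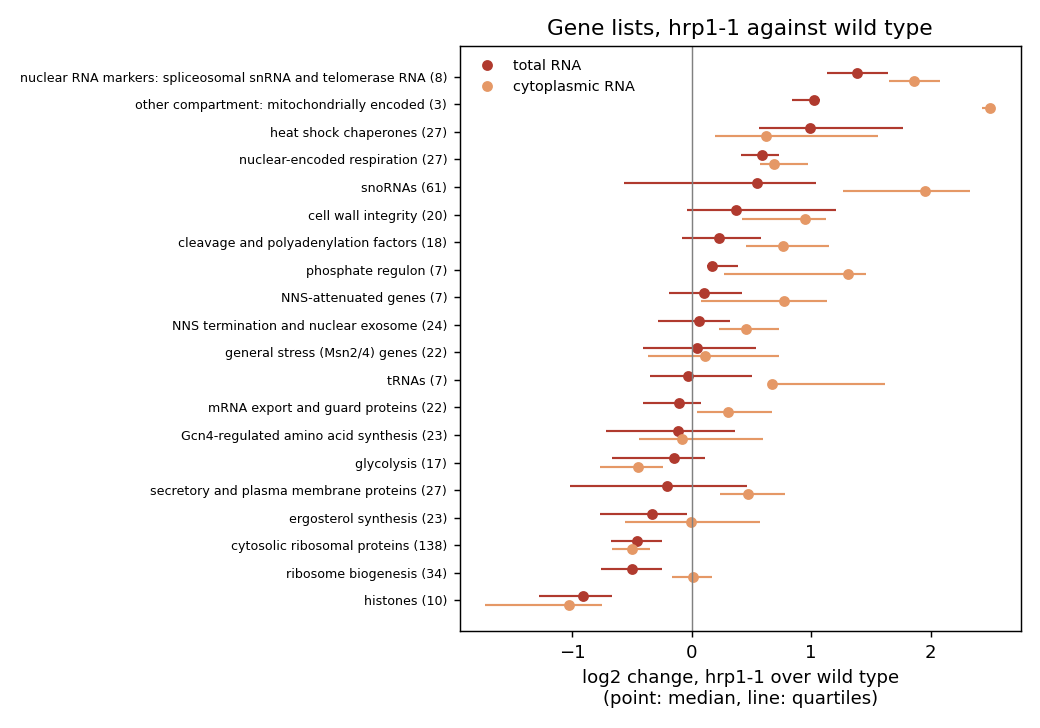
Log2 change of coding coverage (or of RNA coverage for RNA genes) in hrp1-1 over wild type for each gene list, with the number of members, in total and cytoplasmic RNA (points are medians, lines quartiles). Heat shock chaperones lie at 0.99 and 0.62 and histones at -0.91 and -1.03, and the cytoplasmic median of all genes is 0.45.

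The comparison of cytoplasmic with total RNA shows what the fraction holds. In wild type, 15 genes were higher and 531 lower in the cytoplasmic library by at least 1 log2 unit, around a median of all genes of -0.10. That median was 0.11 when scaled by the median of ratios, 0.16 when scaled to all coverage and 0.15 without the 5% most covered genes, with 435, 405 and 413 genes lower. Genes of secretory and plasma membrane proteins (27) had a median of -1.67 in wild type and -0.90 in hrp1-1, percentile 0.0 in both, and 18 and 10 of them lower by at least 1. The endoplasmic reticulum chaperone gene KAR2 was at -2.37 and -2.09, the agglutinin gene AGA1 at -2.28 and -2.14, RTN2 at -2.23 and -2.11, YGP1 at -3.23 and -1.90 and POM33 at -1.87 and -1.98. The a-specific genes (5) were at -2.18 and -0.17, the latter at 0.32 when scaled to all coverage. Among the genes ranked, the highest were KDX1 (3.12 and 1.31), OAZ1 (0.89 and 1.14), HO (0.89 and 1.31), YOL159C-A (0.84 and 1.36) and MIN7 (0.78 and 0.82). CYC1, a member of the respiration list that is not among them, was at 1.07 and 0.88. In hrp1-1, 120 genes were higher and 159 lower, around a median of 0.20, so that the higher share of calls was 43.0%. That share was 16.9% when scaled by the median of ratios and 97.0% when scaled to all coverage.

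For snoRNAs, whose 3' ends are made by NNS termination and trimming, the 3' extension was lower relative to the body in hrp1-1. Over the 33 of 76 snoRNAs that could be used, its median change was -1.03 in total RNA (-1.66 to -0.80) and -1.14 in cytoplasmic RNA (-1.69 to -0.85), with 3 and 1 up and 18 and 18 down by at least 1. The bodies of these snoRNAs changed by medians of 0.66 and 2.12 and their downstream windows by -0.48 and 0.81. SNR47 (chromosome IV, 541602 to 541700, - strand) had the largest rise in both fractions, 2.19 and 1.39, with downstream coverage going from 5.54 to 17.6 in total and from 5.10 to 55.2 in cytoplasmic RNA. The next were SNR87 (0.32 and 0.23), SNR39B (0.05 and 0.43), SNR69 (1.41 and 0) and SNR52 (1.16 and -0.11). The level of 61 snoRNAs changed by medians of 0.55 and 1.95, the first at -0.09 when scaled to all coverage, and that of the 8 nuclear RNA markers by 1.38 and 1.86. SCR1 changed by 1.87 and 1.78, and TLC1 by 0.18 and 1.72, or -0.46 in total RNA when scaled to all coverage.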

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

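The values in this part were picked out after they were seen, and none of the differences was tested, since each group has 1 library. The median of all 4123 genes also had opposite signs, at -0.10 in wild type and 0.20 in hrp1-1, so the lists named next share a direction with genes in general. Genes of cleavage and polyadenylation factors had a median log2 ratio of cytoplasmic over total RNA of -0.16 in wild type and 0.33 in hrp1-1, opposite directions in the genotypes, although the wild type median was above 0 under the other 3 scalings, at 0.06 to 0.11. Their percentiles among matched lists were 44 and 86.7. Genes of mRNA export and guard proteins likewise had -0.14 in wild type and 0.37 in hrp1-1, with the wild type at 0.08 to 0.13 under those scalings and percentiles of 33.1 and 96. The 7 covered tRNA genes had -0.61 in wild type and 0.14 in hrp1-1, with hrp1-1 at -0.06 when scaled by the median of ratios and percentiles of 6.8 and 32.7.

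Coverage on the strand opposite to coding genes, which no comparison of the report uses, was higher in hrp1-1 than in wild type. Over 3627 genes its median normalised coverage was 1.07 in hrp1-1 total and 1.44 in hrp1-1 cytoplasmic RNA, against 0.348 and 0.241 in the wild type libraries. Antisense coverage rose by at least 1 log2 unit for 1373 genes in total and 1974 in cytoplasmic RNA, and fell for 120 and 21. Its per-gene median log2 change was 0.67 in total and 1.12 in cytoplasmic RNA. The readthrough index, which is relative to coding coverage, changed by medians of 1.04 and 1.28. Sense coverage lay above antisense coverage for 97.3% and 96.8% of genes in wild type total and cytoplasmic RNA, and for 94.8% and 94.0% in hrp1-1.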

How the results depend on the processing

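Settings chosen after seeing the data were the window past the farthest listed end, background subtraction, and genes whose next gene lies over 1500 nt away; the others were chosen before the data were examined. The intron index and its alternatives were not run. Of the values that answer a comparison, 92 stayed within the bounds set for them, 84 moved and 2 with a called direction changed sign; of those of single genes and lists, 871, 195 and 2. A change of sign of a value with no called direction counts as moved or kept: the fraction difference of the index in wild type, near 0, is one, as are lists whose other sign stands beside them in the text. Values are given as hrp1-1 over wild type, total before cytoplasmic RNA, unless named as a fraction difference (cytoplasmic minus total RNA). Except where a smaller set of genes or a rescaling itself changes a count, the cause was not tested. The median change of the readthrough index was above 0 in both fractions under every setting run, except in total RNA for the window 50 to 200 nt past the stop codon. Approximate reads limit downstream values near the floor.

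With a pseudocount of 0.1 the median index change was 1.44 and 1.97, with 171 genes down in total RNA; the upstream control was 0.64 and 0.86, and the fraction difference of the index was -0.09 in wild type, 0.38 in hrp1-1 and 0.56 between them. With a pseudocount of 2 these medians were 0.62 and 0.62, with 958 genes up in cytoplasmic RNA, and the fraction differences 0.03, 0.17 and 0.07. With a coverage minimum of 2 the index change was 0.95 and 1.15. With a minimum of 30 it was 1.23 and 1.64, with 665 and 778 genes up and 46 and 15 down among fewer genes; the upstream control was 0.61 and 0.80 and the fraction differences -0.08, 0.41 and 0.51.

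In the window 50 to 200 nt past the stop codon the median index change reversed to -0.03 in total RNA and was 0.27 in cytoplasmic RNA, with 361 and 527 genes up and 166 down in total RNA, and fraction differences of 0.10 in wild type and 0.41 in hrp1-1. CPR1 reversed there to -0.06 in total RNA. In the 250 nt window that skips 250 nt, the change was 1.33 and 1.52 and the fraction difference 0.26 in hrp1-1 and 0.24 between the genotypes. Against the whole coding sequence the change was 0.90 and 1.14. With no gene on either strand downstream, 392 and 416 genes were up and 47 and 23 down among fewer genes, with a cytoplasmic median of 1.15 and a fraction difference of 0.36 in hrp1-1. With the next gene over 1500 nt away, 851 and 967 were up and 62 down in total RNA. Past the farthest listed end the change was 1.35 and 1.46, with 116 down in cytoplasmic RNA, and fraction differences of -0.04, 0.15 and 0.11. After background subtraction it was 0.80 and 0.71, with 183 and 218 down, and the fraction differences were 0.05, 0.10 and, reversed, -0.01.

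For gene level, scaling by the median of ratios gave 379 genes up and 436 down in cytoplasmic RNA, and the ribosome biogenesis list reversed there to -0.48. Fraction counts are given as a percent of the genes used, and were 0.364% higher and 12.9% lower in the fraction in wild type and 2.91% and 3.86% in hrp1-1. Under that scaling 0.853% were higher in wild type, and 1.24% higher and 6.12% lower in hrp1-1. Scaling to all coverage gave 149 up and 1240 down in total and 430 and 380 in cytoplasmic RNA, with 1.14% higher in the fraction in wild type, and 21% higher and 0.656% lower in hrp1-1. Scaling without the 5% most covered genes gave 508 up and 302 down in cytoplasmic RNA, and 1.05% higher in the fraction in wild type. With a coverage minimum of 2, 0.654% were higher in the fraction in wild type and 4.26% in hrp1-1, and with no minimum 0.724% and 4.55%. The first 500 coding nt alone, covered in fewer genes, gave 147 down in total and 532 up in cytoplasmic RNA, 12.8% lower in the fraction in wild type, and 2.45% higher and 3.57% lower in hrp1-1, where the counts moved with the number of genes.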

Other observations

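Tests chosen only after the result was seen were those of uniform background in the rise of the index, of strain markers, of nuclear RNA in the cytoplasmic fraction, and of the other attenuated genes. The background subtraction and the choice of genes with a distant next gene were settings added after seeing the data. The runs of the index by level with other pseudocounts were also added later. The median change of the readthrough index was 0.79 in the lowest and 1.32 in the highest of 5 groups of genes by level in total RNA, and 0.96 and 2.03 in cytoplasmic RNA, where the next to lowest group was at 0.94. The pseudocount lowers the change of genes with little downstream coverage. With a pseudocount of 0.1 the lowest and highest groups were at 1.17 and 1.56 in total and 1.67 and 2.67 in cytoplasmic RNA, and with 2 at 0.44 and 0.92, and 0.30 and 1.36.

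Other gene lists added to the level comparison. Genes of mRNA export and guard proteins (22) changed by medians of -0.11 in total and 0.30 in cytoplasmic RNA, the latter below 0 under the other 3 scalings, and at -0.18 when scaled by the median of ratios. Secretory and plasma membrane protein genes were at -0.21 and 0.47, or -0.02 in cytoplasmic RNA under the latter scaling, with SED1 at 1.72 and 1.15 and GAS1 at -1.52 and -0.25. Gcn4-regulated amino acid synthesis genes (23) were at -0.12 and -0.08, or -0.75 and -0.49 when scaled to all coverage and -0.18 and -0.56 by the median of ratios, with LYS1 at 1.16 and 1.24 and LYS9 at -1.68 and -1.61. Ergosterol synthesis genes (23) were at -0.33 and -0.01, or -0.97 and -0.43 when scaled to all coverage and -0.39 and -0.50 by the median of ratios, with ERG12 at -1.25 and -1.28. The 7 covered genes of the phosphate regulon were at 0.17 and 1.31, the first at -0.45 when scaled to all coverage, with the acid phosphatase gene PHO5 at 0.82 and 1.62. The 7 covered tRNA genes were at -0.03 and 0.67, or -0.64 and 0.27 when scaled to all coverage.

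The readthrough index was higher in hrp1-1 in both fractions. Background spread evenly over the libraries would add the same coverage at every gene. The excess of downstream coverage in the highest of 5 level groups was 4.34 times that in the lowest in total RNA (3.06 to 5.70). In cytoplasmic RNA it was 3.80 times (2.92 to 4.63). This argues against even background as the whole cause. The median level of these groups was 160.4 and 13.1, so the excess rose less than the level did. Even background as part of the cause therefore stays open. Lower depth is argued against by wild type reads thinned to the hrp1-1 depth, which changed the index by -0.01 and 0. Transcripts starting at the next gene are argued against by 1696 genes whose next gene on the strand lies over 1500 nt away, with changes of 1 and 1.27. Strain differences other than hrp1-1 stay open, since 7 markers separate the genotypes and no library separates them from the mutation, and so does an effect of the mutation, which may extend transcripts. A rise of coverage that is not confined to 3' ends stays open too. Antisense coverage rose by medians of 0.67 and 1.12, and the upstream control by 0.49 and 0.56. Both can also hold RNA extended from a neighbouring gene, so they cannot decide this.

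The index was also higher in cytoplasmic than in total RNA of hrp1-1, by a median of 0.30. After background subtraction 0.10 was left (0.06 to 0.14). The subtracted coverage came from the opposite strand, which may itself hold RNA. It varied widely between windows, with quartiles of 0.567 and 5.8 in hrp1-1 cytoplasmic RNA. The subtraction therefore cannot tell how much of the difference is uniform background, which stays open. Nuclear RNA carried into the fraction also stays open. The nuclear RNAs had a median of -0.16 with an interval that spans 0 (-0.31 to 0.30). Most of them were snoRNAs, 61 with a median of 0.12, while the 8 other nuclear RNA markers were at -1.26. The cytoplasmic marker SCR1 was also low in the fraction. Export of extended RNA, which the design asks about, was not separated from either.

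HRP1 was covered more in hrp1-1. A genomic fragment carrying its neighbours is argued against, since the highest change of TRM11 and SMF1 in either fraction was 0.11. A loss of attenuation shared with the other attenuated genes is argued against by their median change of -0.04 in total RNA (range -1.77 to 0.51, n = 6). Extra copies of HRP1 alone, for example on a plasmid with a marker, and a change in the control of HRP1 alone may each give this, and neither was tested.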
